A study of Mus musculus with 145 samples.

How the data were processed

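Per the labels, RNA was taken up in TRIzol and total RNA was labelled with biotin and put on Affymetrix arrays. Per the submitters' processing notes, the deposited intensity values were made with Affymetrix Power Tools and RMA. The version, the background setting, and whether all arrays were normalized together, are not given in the sources used here. The deposited values give 1 linear intensity per probe set and array, for 24922 probe sets. From the values, all are positive and array maxima lie between 14147 and 25426, so the log2 was taken here. By the annotation supplied with the values, 21425 probe sets carried 1 gene symbol (19752 distinct symbols), 1399 carried several and 2098 were not listed. Symbols and gene identifiers were compared with RefSeq gene records, which renamed 0 of them. No array repeated another.

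Each comparison was tested with limma (lmFit and eBayes, two-sided) in R, with a mean per group. The 34 comparisons came from 15 fits, each of groups that belong together by their titles, such as 22 arrays for the stimulated T cells. A probe set entered a fit when its highest group mean reached the median of all values on the arrays of the fit, which left between 12837 and 15042. P-values were adjusted by Benjamini-Hochberg over the probe sets of the fit within each comparison. A probe set was called at an adjusted p under 0.05, and the count with at least a 2-fold difference is given beside it. Groups of 2 borrow their spread from the other groups of the fit, and a lone array left by a leave-out is assumed to vary like the other groups.

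Genes were also tested as lists, 33 of processes and cell states and 21 of cell type markers, written before the data were examined. Camera of limma compared each list of at least 3 tested genes with all other genes of the fit, with a preset correlation between genes of 0.01 and again with an estimated correlation. The gene's probe set with the highest mean over the fit was used, and p-values were adjusted over the lists of a comparison. Over all comparisons 584 lists were tested, 241 passed with the preset and 70 with the estimated correlation, all 70 of them among the 241, of which the text names a part. The text names the lists that bear on the question of a comparison. Some list members had no probe set with a single symbol and were not analysed here.

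Genes were named by a rule also written before the data were examined. It took the 5 largest rises and 5 largest falls among called probe sets with a single symbol whose groups did not overlap, without predicted genes, small RNAs and receptor or immunoglobulin segments. It added up to 4 called members per list and the genes in the group labels. Names in the text were drawn from these, except Igkv6-20, an immunoglobulin segment named after its values were seen because it was the only call in FRC with CFA. Names in the closing part follow its tests.

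Replicate numbers were checked as a possible pairing. Deviations of arrays from their group mean were correlated between groups for equal numbers, over 32 pairs of groups, of which 10 shared 3 or more numbers. Equal numbers deviated alike in 2 of these, GFP+ and GFP- medullary cells (r from 0.20 to 0.52) and liver macrophages (r from 0.13 to 0.47). Groups that share fewer than 3 numbers, among them 14 pairs of groups with 2 arrays and 2 shared numbers each, do not decide the question. In fat the numbers go with the age in days in the labels, although equal numbers of macrophages and CD11b+ cells deviated oppositely (r from -0.63 to -0.30). In cortical against medullary epithelium the same numbers deviated oppositely (r = -0.24). The fits reported have no block, and fits with a block are among the alternatives.

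The alternatives were no filter or a stricter filter (75th percentile) on dim probe sets, quantile normalization within the fit, log2 of the intensity plus 32, all arrays of the series in a single fit, limma with trend and robust variances, a block for replicate number, and each replicate left out. For mast cells the 2 arrays with blood as source, or the array with unfilled markers, were left out as well. Tested on simulated data in 5 comparisons, with 200 changed genes put into each, the fits recovered between 0 and 34.0% of those with a log2 change of 0.5 (0% for KLRG1, 14.0% for FRC with CFA), between 34.0 and 88.0% at a change of 1, and between 72.0 and 100% at a change of 2, with 2 to 9 false calls. The lowest recovery at each of these changes was that of the KLRG1 comparison. Versions used were R 4.3.3, limma 3.58.1 and, to read files, 1.17.8 of data.table.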

Results

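Gene expression was measured on Affymetrix arrays of sorted mouse cells, in 65 groups set by cell type, organ, age, genotype or treatment. 12 groups held 1 array, 28 held 2, 23 held 3 and 2 held 4. The median intensity of an array lay between 112 and 147 and its highest between 14147 and 25426. Arrays of the same group correlated across probe sets with r between 0.922 and 0.9967 (median 0.992), which says nothing about independent replicates because genes are not independent. The comparisons used 125 arrays of 49 groups, and the 2 to 4 arrays per group limit their precision. Changes are given as log2 fold changes ± SE, a gene was called at an adjusted p under 0.05, and intensities are means over the arrays of a group. Xist lay at 58.0 or below in arrays labelled male that lack it. A change with a group at or below that level is marked as over, to or at background, since the floor affects its size. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples.

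**Figure D1:**
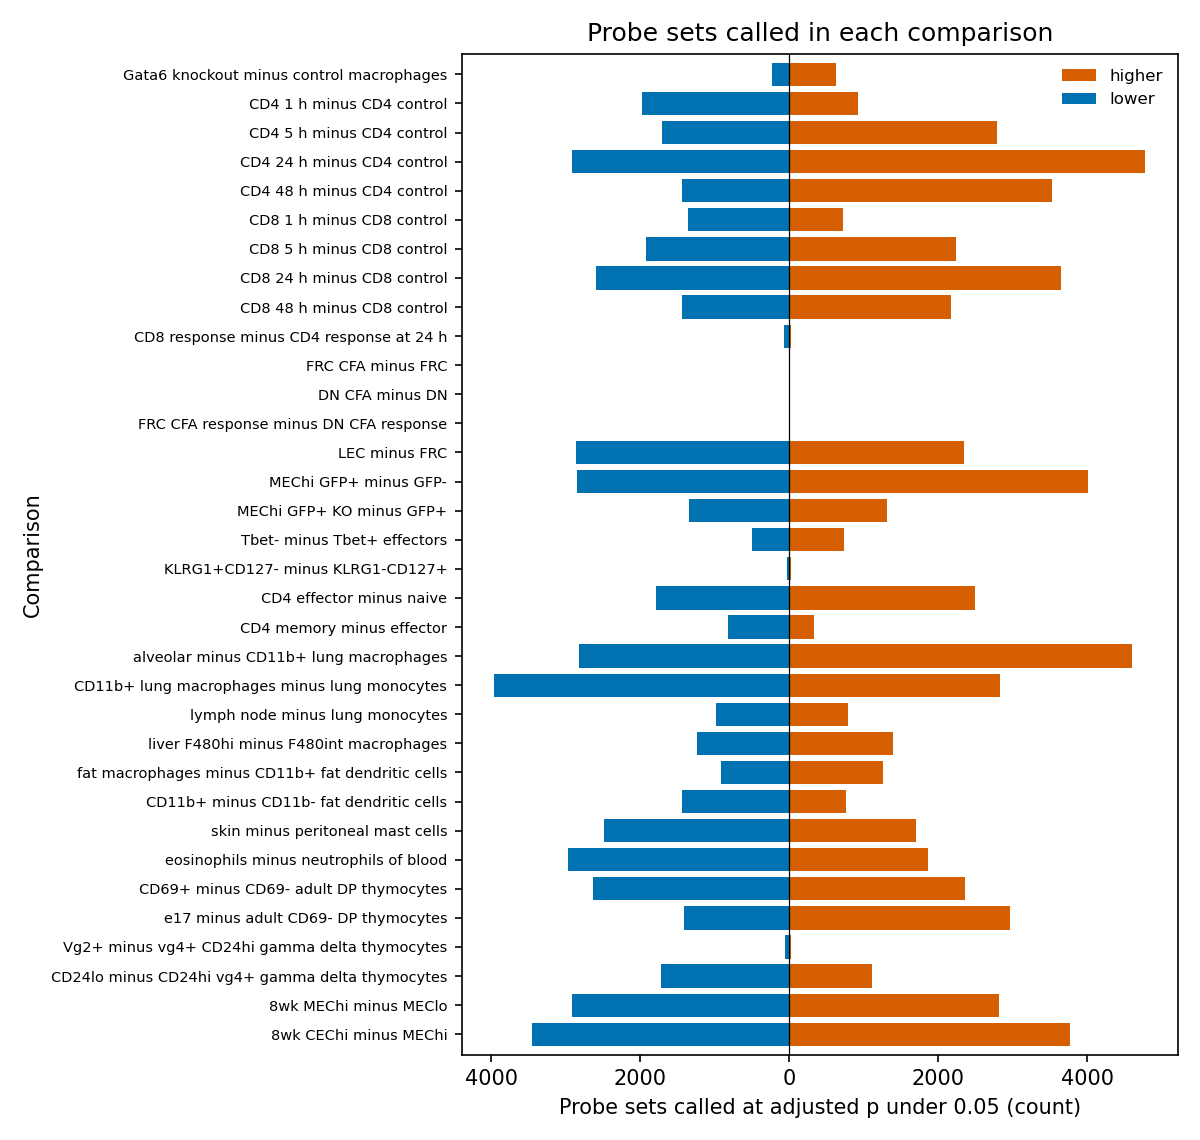
Number of probe sets called in each comparison (horizontal axis, count), higher to the right and lower to the left of 0, with a row for each of the 34 comparisons. The responses of stroma to CFA have the fewest calls, 1 in FRC and 12 in DN cells, and CD4 cells at 24 h the most, 7692.

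The first question was which genes change in naive lymph node T cells within 1 h of culture with CD3 and CD28 antibody beads. The unstimulated controls (n = 2 arrays per group), shared by all times, carry no culture time, so effects of beads and culture are not separated. Nr4a3, which encodes a nuclear receptor induced by T cell receptor signals, rose by 4.39 ± 0.16, adjusted p = 1.6e-10 in CD4 cells, from an intensity of 199 to 4178. In CD8 cells it rose by 4.38 ± 0.16 and its relative Nr4a1 by 4.13 ± 0.13. Among immediate early and stress genes in CD4 cells, 8 of 15 rose and 2 fell (8 and 3 adjusted over the list alone), and in CD8 cells 9 of 15 rose and 1 fell (10 and 1 adjusted over the list alone). Interferon response genes moved down, as 9 of 13 fell (10 adjusted over the list alone) in CD4 cells and 9 of 13 fell (13 adjusted over the list alone) in CD8 cells. Usp18, a protease that dampens interferon receptor signals, fell by a log2 change of -2.62 ± 0.14 in CD4 and -2.35 ± 0.14 in CD8 cells. Each list shifted as a set, the immediate early genes with camera adjusted p = 5.8e-07 in CD4 and 1.1e-12 in CD8 cells, adjusted p = 0.042 and 0.0076 with an estimated correlation. The interferon genes gave camera adjusted p = 1.4e-06 and 1.7e-08, again 0.042 and 0.0076 with an estimated correlation. CD4 cells changed 2903 of 14411 probe sets, 920 higher and 1983 lower, 536 at least 2-fold, and CD8 cells 2089 of 14411 probe sets, 723 higher and 1366 lower, 373 at least 2-fold. Quantile normalization gave 1394 higher and 1849 lower in CD4 cells, and 910 and 1110 in CD8 cells. The CD4 count was 1397 without stimulated replicate 2. The CD8 count was 1016 and 1153 without stimulated replicates 1 and 2, and 1375 and 958 without control replicates 1 and 2.

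After 5 h (n = 2 per group), of the T cell cytokine genes 6 of 11 rose and 1 fell (6 and 1 adjusted over the list alone) in CD4 cells and 7 of 11 rose (7 adjusted over the list alone) in CD8 cells (camera adjusted p = 0.0013 in CD4 and 1.2e-07 in CD8 cells, adjusted p = 0.03 and 0.0032 with an estimated correlation). In CD4 cells Il2, a T cell growth factor, rose by 5.25 ± 0.38 over background, adjusted p = 4.9e-08, and Il2ra, the inducible chain of its receptor, by 5.12 ± 0.21. In CD8 cells Il2ra rose by 6.57 ± 0.21 over background, adjusted p = 5.2e-12, and the chemokines Xcl1 and Ccl3 by 6.11 ± 0.19 and 5.73 ± 0.16. Ccl3 went from an intensity of 68.0 to 3595. The transcription factor gene Irf4 rose by 5.03 ± 0.13 in CD4 and 4.94 ± 0.13 in CD8 cells, and Igfbp4, a growth factor binding protein of resting cells, fell by log2 changes of -3.98 ± 0.13 and -3.74 ± 0.13. Of the activation receptor genes 10 of 14 rose (10 adjusted over the list alone) in CD4 cells and 11 of 14 rose (12 adjusted over the list alone) in CD8 cells (camera adjusted p = 3.5e-09 in CD4 and 1.2e-10 in CD8 cells, adjusted p = 0.0011 and 5.0e-04 with an estimated correlation). Of the ribosome biogenesis genes 13 of 13 rose (13 adjusted over the list alone) in CD4 cells and 13 of 13 rose (13 adjusted over the list alone) in CD8 cells (camera adjusted p = 2.1e-11 in CD4 and 6.2e-10 in CD8 cells, adjusted p = 0.006 and 0.0079 with an estimated correlation). For cholesterol synthesis 10 of 11 rose and 1 fell (10 and 1 adjusted over the list alone) in CD4 cells (camera adjusted p = 1.1e-06, adjusted p = 0.03 with an estimated correlation). Of the interferon response genes 12 of 13 fell (13 adjusted over the list alone) in CD4 and 12 of 13 fell (12 adjusted over the list alone) in CD8 cells (camera adjusted p = 2.1e-11 in CD4 and 6.0e-13 in CD8 cells, adjusted p = 0.0031 and 0.0019 with an estimated correlation). Of the cell cycle genes 2 of 20 rose in CD8 cells, and the set test did not pass (camera adjusted p = 0.86). Markers of immature thymocytes were lower in CD8 cells at 1 h and in both cell types at 5 h (camera adjusted p from 0.026 to 0.04, adjusted p from 0.063 to 0.084 with an estimated correlation). The totals were 4495 of 14411 probe sets, 2783 higher and 1712 lower, 1296 at least 2-fold for CD4 cells, and 4163 of 14411 probe sets, 2233 higher and 1930 lower, 1121 at least 2-fold for CD8 cells. Quantile normalization gave 2419 higher and 2216 lower in CD4 cells, and 2194 and 2118 in CD8 cells.

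At 24 h the question was how far the cells had entered division and effector programs (n = 2 per group). Every tested cell cycle gene rose in CD4 and in CD8 cells, 20 and 20 genes, with the same numbers adjusted over the list alone (camera adjusted p = 1.3e-14 in CD4 and 6.3e-19 in CD8 cells, adjusted p = 0.0018 and 6.8e-04 with an estimated correlation). Ccna2, a cyclin of S and G2 phase, rose by 5.21 ± 0.26 over background, adjusted p = 3.7e-10 in CD4 and 5.23 ± 0.26 in CD8 cells. Il2ra stood 5.37 ± 0.21 and 7.10 ± 0.21 over background above control. All glycolysis genes tested rose, 10 in CD4 and 10 in CD8 cells, with the same numbers adjusted over the list alone (camera adjusted p = 8.4e-07 in CD4 and 4.9e-07 in CD8 cells, adjusted p = 0.0018 and 0.0016 with an estimated correlation). S1pr1, a receptor for lymph node exit, fell by log2 changes of -3.39 ± 0.12 and -2.92 ± 0.12, and its regulator Klf2 by -2.09 ± 0.14 and -2.16 ± 0.14. Of the naive and memory genes 8 of 14 fell (8 adjusted over the list alone) in CD8 cells, with camera adjusted p = 2.7e-05, adjusted p = 0.054 with an estimated correlation. Platelet markers were lower in CD4 cells, 3 of 4 (camera adjusted p = 0.031, adjusted p = 0.18 with an estimated correlation). Dendritic cell markers were lower in CD8 cells, 2 of 3, Itgae among them (camera adjusted p = 0.043, adjusted p = 0.089 with an estimated correlation). CD4 cells changed 7692 of 14411 probe sets, 4774 higher and 2918 lower, 2641 at least 2-fold, and CD8 cells 6239 of 14411 probe sets, 3647 higher and 2592 lower, 2082 at least 2-fold. Quantile normalization moved the CD4 median by -0.12 and gave 3686 higher and 3807 lower there. In CD8 cells it gave 3207 higher and 3277 lower.

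Whether CD8 cells responded differently from CD4 cells at 24 h was tested as the difference between the responses (n = 2 in each of 4 groups). Gzmb, a protease of killer cells, rose more in CD8 cells by 4.00 ± 0.22 with CD4 cells at background, adjusted p = 1.3e-07, from 62.6 to 1110 in CD8 cells while it stood at 44.0 and 48.9 in control and stimulated CD4 cells. Xcl1 and Ccl3 also rose more in CD8 cells, by 3.66 ± 0.27 and 2.40 ± 0.23, as did the inhibitory receptor gene Tigit by 2.33 ± 0.29. The response of CD4 cells was the stronger for Il2rb, a shared chain of cytokine receptors (-2.71 ± 0.26, adjusted p = 3.7e-05), and for the costimulatory receptor gene Tnfrsf4 (-1.86 ± 0.22). The integrin gene Itgae (-2.66 ± 0.23) went from 1927 to 306 in CD8 cells and stood at 60.2 and 60.5 in control and stimulated CD4 cells, so near the floor that no fall could have been seen there. The responses differed for 95 of 14411 probe sets, 28 higher and 67 lower, 75 at least 2-fold. Of 20 cell cycle genes limma called 0, 8 had an unadjusted p under 0.05, and 3 responded less in CD8 cells adjusted over the list alone (camera adjusted p = 0.85). Dendritic cell markers moved toward CD4 cells, 1 of 3, which was Itgae (camera adjusted p = 0.0024, adjusted p = 0.055 with an estimated correlation), and platelet markers toward CD8 cells, 1 of 4 (camera adjusted p = 0.025, adjusted p = 0.21 with an estimated correlation). T cell cytokine genes went both ways, 3 toward CD8 and 2 toward CD4 cells of 11 (4 and 3 adjusted over the list alone). Their median was -0.02, 0.10 after quantile normalization, although camera placed the list up (camera adjusted p = 0.025, adjusted p = 0.19 with an estimated correlation). The count was 47 without CD4 24 h replicate 2, 52 and 50 without CD8 24 h replicates 1 and 2, and 49 and 54 without CD8 control replicates 1 and 2.

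At 48 h all 20 cell cycle genes tested stood above control in CD4 cells and all 20 in CD8 cells (n = 2 per group), with the same numbers adjusted over the list alone (camera adjusted p = 2.0e-25 in CD4 and 1.5e-32 in CD8 cells, adjusted p = 3.8e-04 and 1.3e-04 with an estimated correlation). Ccna2 was up by 6.14 ± 0.26 over background, adjusted p = 4.7e-11 in CD4 and 5.65 ± 0.26 in CD8 cells, and Kif11, a motor of the spindle, by 5.53 ± 0.20 over background and 5.64 ± 0.20 over background. Gzmb was up by 3.73 ± 0.16 in CD8 cells. Immediate early genes now lay below control, as 1 of 15 rose and 11 fell (1 and 11 adjusted over the list alone) in CD4 and 11 of 15 fell (12 adjusted over the list alone) in CD8 cells, among them Rgs2, a brake on receptor signalling (-3.32 ± 0.29 and -3.29 ± 0.29 to background). As sets they gave camera adjusted p = 1.6e-06 in CD4 and 3.4e-10 in CD8 cells, adjusted p = 0.024 and 0.0057 with an estimated correlation. Ribosome biogenesis genes, up at 5 and 24 h, were down in CD8 cells, where 9 of 13 fell (11 adjusted over the list alone), with camera adjusted p = 1.3e-06, adjusted p = 0.02 with an estimated correlation. Dtx1, a regulator of Notch signalling, fell by a log2 change of -3.59 ± 0.14 there. Changes reached 4973 of 14411 probe sets, 3529 higher and 1444 lower, 1270 at least 2-fold in CD4 cells, and 3606 of 14411 probe sets, 2168 higher and 1438 lower, 972 at least 2-fold in CD8 cells. Quantile normalization gave 2504 higher and 2689 lower in CD4 cells, with a median shift of -0.14, and 1949 and 1995 in CD8 cells. The counts fell to 2934 without CD4 48 h replicate 2 and to 2268 without CD8 48 h replicate 1.

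**Figure D2:**
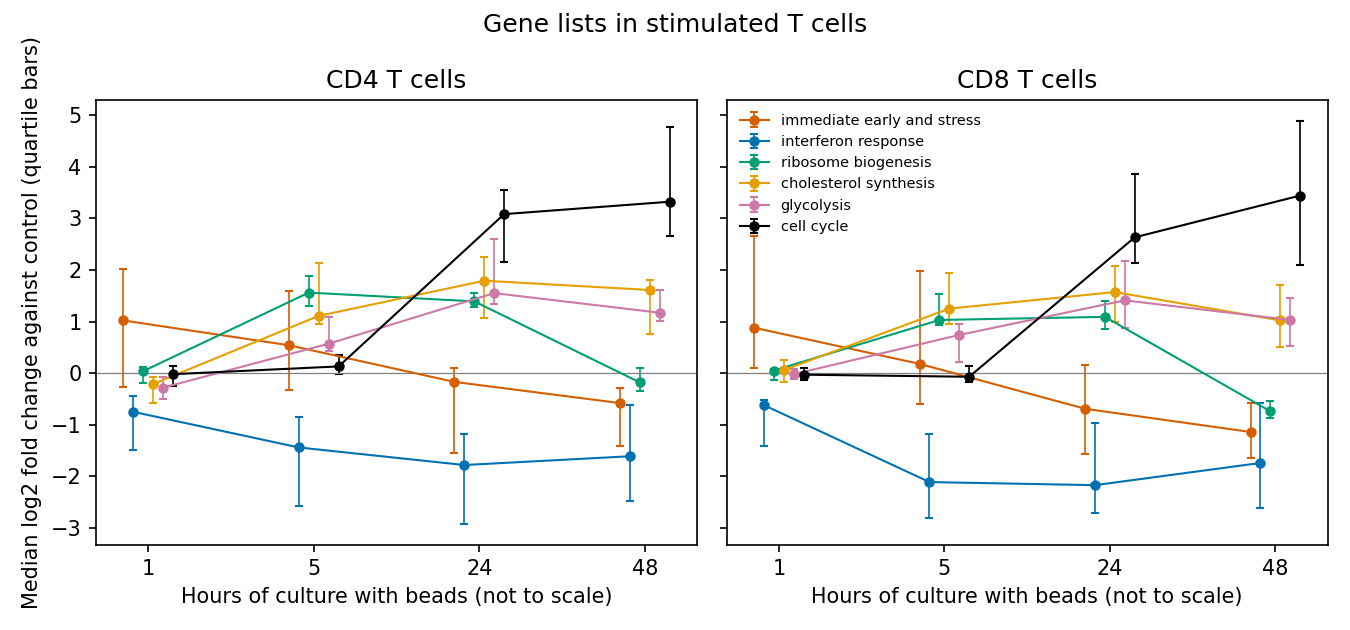
Median log2 fold change (log2 units, vertical axis) of 6 gene lists against hours of culture with CD3 and CD28 beads (1, 5, 24 and 48 h), for CD4 cells on the left and CD8 cells on the right, with bars from the lower to the upper quartile of the list. Interferon response genes lie below 0 at every time in both cell types, and cell cycle genes rise at 24 and 48 h.

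In spleen CD4 cells after infection with lymphocytic choriomeningitis virus, the labels separate naive cells, day 8 effectors and day 30 memory cells (n = 2 each). Effectors held Nkg7, a protein of cytotoxic granules, at 9224 against 85.5 in naive cells (6.75 ± 0.14, adjusted p = 6.1e-08). Gzmb was higher by 6.68 ± 0.18 over background, the chemokine gene Ccl5 by 5.92 ± 0.18 and Tbx21, the transcription factor of Th1 cells, by 4.63 ± 0.14. Cd44, a sort marker, was higher by 2.49 ± 0.13. Igfbp4 was lower (-4.96 ± 0.12), as were the homing receptor gene Ccr7 (-2.76) and Il7r, a survival receptor (-2.58 ± 0.13). Of the Th1 genes 12 of 12 were higher (12 adjusted over the list alone), of the cytotoxic effector genes 12 of 14 were higher (14 adjusted over the list alone), and of the cell cycle genes 19 of 20 were higher (20 adjusted over the list alone) (camera adjusted p from 2.5e-16 to 5.8e-12, adjusted p from 0.2 to 0.21 with an estimated correlation). Follicular helper genes also moved, as 7 of 9 were higher and 1 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 2.9e-04, adjusted p = 0.34 with an estimated correlation. Of the naive and memory genes 11 of 14 were lower (11 adjusted over the list alone), with camera adjusted p = 1.2e-09, adjusted p = 0.2 with an estimated correlation. The difference covered 4291 of 13332 probe sets, 2496 higher and 1795 lower, 1127 at least 2-fold, and 2573 without effector replicate 2. Quantile normalization gave 2427 higher and 2466 lower.

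Memory cells compared with effectors showed which of these changes had receded by day 30. Il7r stood higher by 3.02 ± 0.13, adjusted p = 9.7e-06, at 7412 against 914 in effectors, and the chemokine receptor gene Ccr4 by 2.50 ± 0.13. Gzmb was lower (-4.90 ± 0.18, adjusted p = 5.3e-06), as were Havcr2, an inhibitory receptor (-3.87 ± 0.12), and Bub1, a mitotic checkpoint kinase (-2.76 ± 0.20 to background). Cd44 did not differ (0.20 ± 0.13, adjusted p = 0.38). Of the cell cycle genes 19 of 20 were lower (20 adjusted over the list alone), of the cytotoxic effector genes 10 of 14 were lower (11 adjusted over the list alone) and of the Th1 genes 8 of 12 were lower (9 adjusted over the list alone) (camera adjusted p from 1.2e-22 to 2.5e-08, adjusted p from 0.22 to 0.25 with an estimated correlation). Naive and memory genes were up, as 5 of 14 were higher (8 adjusted over the list alone, with 1 lower), at camera adjusted p = 8.4e-06, adjusted p = 0.22 with an estimated correlation. In all 1147 of 13332 probe sets, 327 higher and 820 lower, 354 at least 2-fold differed. Quantile normalization gave 641 higher and 853 lower. Without effector replicates 1 and 2 the count was 650 and 501, and without memory replicates 1 and 2 it was 450 and 583.

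CD8 effectors titled OT1, Tbet- against Tbet+, were compared 6 days after Listeria (LisOVA) infection (n = 3 each). Its gene Tbx21 was lower in Tbet- cells (-3.44 ± 0.11, adjusted p = 4.6e-08), at 292 against 3169. Klrg1, a receptor of terminal effectors, was also lower (-4.76 ± 0.14, adjusted p = 4.3e-08), as were the exit receptor gene S1pr5 (-4.57 ± 0.12), the transcription factor gene Zeb2 (-4.35 ± 0.13 to background) and the granzyme gene Gzma (-2.64 ± 0.21). The potassium channel gene Kcnma1 was higher by 7.63 ± 0.11 over background, adjusted p = 1.3e-10, at 6912 against 34.8. Ccr4 and Itgae were higher by 3.41 ± 0.11 and 3.27 ± 0.12. Cd8a did not differ (-0.11 ± 0.10, adjusted p = 0.61). Of the cytotoxic effector genes 12 of 15 were lower (14 adjusted over the list alone), with camera adjusted p = 1.4e-25, adjusted p = 0.041 with an estimated correlation. Markers of NK cells, which share Eomes, Gzma and Prf1 with this list, were lower too, 4 of 5 (4 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.041 with an estimated correlation). Markers of dendritic cells were higher, 2 of 3 (3 adjusted over the list alone, camera adjusted p = 8.2e-06, adjusted p = 0.041 with an estimated correlation), with Itgae and Ccr7 called. Among naive and memory genes 6 of 14 were higher (10 adjusted over the list alone), with camera adjusted p = 1.6e-05, adjusted p = 0.041 with an estimated correlation. In the cell cycle list 9 of 20 were lower (12 adjusted over the list alone), with camera adjusted p = 1.7e-08, adjusted p = 0.25 with an estimated correlation. The labels give the groups different CD45 alleles, a difference that runs with the genotype. 1243 of 12837 probe sets, 735 higher and 508 lower, 288 at least 2-fold differed, with 696, 647 and 697 without Tbet- replicates 1, 2 and 3.

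At day 8 after LisOVA (not titled OT1), KLRG1+CD127- cells (n = 2), short-lived effectors by their sort, were set against KLRG1-CD127+ memory precursors (n = 3). Of the sorted markers Klrg1 was higher by 4.73 ± 0.19, adjusted p = 2.1e-05, and Il7r, which encodes CD127, lower (-4.18 ± 0.21, adjusted p = 4.4e-05) at 279 against 5068. Gpx8, a peroxidase of the endoplasmic reticulum, was higher (over background, adjusted p = 4.4e-05) at 1255 against 56.1. Dapl1, a gene of quiescent T cells, was lower (-3.22 ± 0.21). Of the cytotoxic effector genes 5 of 15 were higher (8 adjusted over the list alone), with camera adjusted p = 4.9e-20, adjusted p = 0.031 with an estimated correlation. NK cell markers moved with them, 1 of 6 higher (3 adjusted over the list alone) at a median of 0.95, with camera adjusted p = 1.3e-06, adjusted p = 0.13 with an estimated correlation. In the naive and memory list 2 of 14 were lower (5 adjusted over the list alone), with camera adjusted p = 3.1e-07, adjusted p = 0.33 with an estimated correlation. In all 50 of 13088 probe sets, 20 higher and 30 lower, 50 at least 2-fold were called, and 996 passed an unadjusted p under 0.05. A single fit of all arrays gave 1036 calls. The count was 33 without a filter on dim probe sets and 79 with trend and robust variances. It was 6 and 15 without KLRG1+ replicates 2 and 3, 8 and 27 without CD127+ replicates 2 and 3. Replicate 3 of each group lacked Xist, a transcript of the inactive X chromosome, which the other 3 arrays held, and a block for this split, chosen after the values were seen, gave 37 calls. A block for replicate number, which contains this split, gave 127, with all 50 among them, on 1 residual degree of freedom.

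In adult thymus the labels set CD69+ against CD69- CD4+CD8+ thymocytes (n = 3 each). Cd69 itself was higher by 3.59 ± 0.09, adjusted p = 4.2e-12, at 3426 against 284. Itm2a, a membrane protein induced at selection, was higher by 4.32 ± 0.10, Nr4a3 by 4.55 ± 0.11 and the chemokine receptor gene Ccr7 by 3.23. Rag1 and Rag2, which cut receptor genes for rearrangement, were lower (-2.30 ± 0.10 and -2.81 ± 0.13), as was Ncapg, a chromosome condensation gene (-3.68 ± 0.12). Of the positive selection genes 16 of 16 were higher (16 adjusted over the list alone), of the cell cycle genes 20 of 20 were lower (20 adjusted over the list alone) and of the immature thymocyte genes 8 of 8 were lower (8 adjusted over the list alone). These lists also moved as sets (camera adjusted p from 1.3e-21 to 3.6e-07, adjusted p = 0.0086 for each with an estimated correlation). Immediate early genes were up, as 12 of 15 were higher (12 adjusted over the list alone), with camera adjusted p = 7.6e-10, adjusted p = 0.0086 with an estimated correlation. 4992 of 13287 probe sets, 2360 higher and 2632 lower, 942 at least 2-fold differed. Quantile normalization gave 2670 higher and 2612 lower.

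CD69- thymocytes from embryonic day 17 were set against those of adults (n = 3 each). The day is that of the titles, and the age label of the same arrays reads 5 weeks. Dntt, the enzyme that adds bases at receptor gene joints, was lower in fetal cells (-4.92 ± 0.11, adjusted p = 2.1e-12), at 116 against 3520. The RNA-binding protein genes Lin28b, Igf2bp3 and Igf2bp1, part of the fetal program, were higher by 1.98 ± 0.17 over background, 2.40 ± 0.18 and 1.70 ± 0.12. Xist was higher (6.07 ± 0.21 over background, adjusted p = 4.8e-10), from 32.4 to 2181, and the fetal arrays are labelled as mixed in sex against male adults. Of the fetal genes 5 of 6 were higher (5 adjusted over the list alone), with camera adjusted p = 2.8e-04, adjusted p = 0.13 with an estimated correlation. Of the cell cycle genes 18 of 20 were higher (18 adjusted over the list alone), with camera adjusted p = 8.2e-08, adjusted p = 0.13 with an estimated correlation. 4376 of 13287 probe sets, 2964 higher and 1412 lower, 335 at least 2-fold differed. Quantile normalization gave 2205 higher and 1946 lower. A single fit of all arrays gave 2841.

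Fetal gamma delta thymocytes of embryonic day 17 were sorted by receptor chain and by CD24, which is lost on maturation. Their day too is that of the titles, against an age label of 5 weeks. Among CD24hi cells, Vg2+ cells against vg4+ cells (n = 3 each) differed in few genes. Il23r, the receptor of the cytokine IL-23, was lower in Vg2+ cells (-2.47 ± 0.08 to background, adjusted p = 2.1e-08), at 34.7 against 193. The cytokine genes Il17f and Il17a were lower too (-1.88 ± 0.13 and -1.03 ± 0.14). Bex6, a signalling adaptor, was higher by 1.12 ± 0.11, adjusted p = 7.7e-04. Of the genes of IL-17-producing gamma delta cells 0 of 13 were higher and 5 lower (3 and 7 adjusted over the list alone), with camera adjusted p = 1.8e-05, adjusted p = 0.27 with an estimated correlation. In all 83 of 13013 probe sets, 25 higher and 58 lower, 14 at least 2-fold differed, and 47 in a single fit of all arrays. The count was 53, 27 and 23 without Vg2+ replicates 1, 2 and 3, and 132 and 48 without vg4+ replicates 2 and 3. The vg4+ label stands for cells negative for 4 other chains.

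CD24lo vg4+ cells (n = 2) were set against CD24hi vg4+ cells (n = 3). Cd24a was lower (-4.15 ± 0.11, adjusted p = 7.3e-10), at 131 against 2324, and Sox4, a transcription factor of immature cells, by a log2 change of -2.30 ± 0.12. Il23r rose to 3938 against 193 (4.35 ± 0.09, adjusted p = 1.2e-10), Il18r1, another cytokine receptor, by 3.21 ± 0.13, and Il17a by 2.28 ± 0.16. The IL-17 list went both ways, as 8 of 13 were higher and 4 lower (8 and 4 adjusted over the list alone), with camera adjusted p = 0.036, adjusted p = 0.41 with an estimated correlation. Of the interferon response genes 6 of 11 were lower (8 adjusted over the list alone), with camera adjusted p = 0.0031, adjusted p = 0.4 with an estimated correlation. Dendritic cell markers were lower too, 2 of 3 (camera adjusted p = 0.036, adjusted p = 0.37 with an estimated correlation). 2837 of 13013 probe sets, 1111 higher and 1726 lower, 407 at least 2-fold differed, 1350 in a single fit of all arrays, 1334 and 1686 without CD24lo replicates 1 and 2. Quantile normalization gave 1385 higher and 1491 lower.

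Thymic epithelium of 8 weeks was sorted into medullary cells high and low for MHC class II and into cortical cells (n = 2 each). These groups follow the titles, since the marker labels are the same for all of them. Medullary high were set against low cells. Aire, the regulator that lets these cells transcribe genes of other organs, was higher by 3.90 ± 0.34, adjusted p = 3.8e-06, at 4074 against 272. The chemokine gene Ccl22 was higher by 4.34 ± 0.24, the casein gene Csn2 of milk by 4.46 ± 0.31 and Tac2, a neuropeptide gene, by 5.08 ± 0.21 over background. Il7, a growth factor for thymocytes, was lower (-2.16 ± 0.21), as was the parathyroid hormone gene Pth (-3.80 ± 0.35). Of the peripheral tissue antigen genes 11 of 14 were higher and 1 lower (11 and 1 adjusted over the list alone), with camera adjusted p = 5.0e-06, adjusted p = 0.17 with an estimated correlation. Of the cell cycle genes 16 of 19 were higher (17 adjusted over the list alone), with camera adjusted p = 5.1e-08, adjusted p = 0.22 with an estimated correlation. Markers of other organs were up as well, with 6 of 6 hepatocyte genes (6 adjusted over the list alone, camera adjusted p = 1.9e-05, adjusted p = 0.15 with an estimated correlation). So were marker lists of neutrophils, eosinophils, mast cells, platelets, macrophages, dendritic cells and immature thymocytes (camera adjusted p from 0.0062 to 0.033, adjusted p from 0.15 to 0.22 with an estimated correlation). Those of fat, lung, skin and mesothelium moved alike (camera adjusted p from 7.0e-04 to 0.033, adjusted p from 0.15 to 0.21 with an estimated correlation). 5733 of 15042 probe sets, 2813 higher and 2920 lower, 2704 at least 2-fold differed.

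In cortical against medullary high cells, Psmb11, a proteasome subunit of cortical epithelium, was higher in cortical cells by 4.98 ± 0.22, adjusted p = 2.3e-08, at 3505 against 111, and the chemokine gene Cxcl12 by 5.14 ± 0.19. Prss16, a thymic serine protease, was higher by 3.73 ± 0.32. Aire was lower (-4.90 ± 0.34, adjusted p = 3.7e-07), at 137 against 4074, as were Mucl2, a secreted mucin-like gene (-7.37 ± 0.55 to background), and Spib, a transcription factor gene (-4.80). Of the cortical genes 11 of 13 were higher (11 adjusted over the list alone), and of the medullary genes 14 of 15 were lower (14 adjusted over the list alone) (camera adjusted p from 8.6e-09 to 2.7e-06, adjusted p = 0.077 for each with an estimated correlation). All 14 peripheral tissue antigen genes tested were lower, 14 adjusted over the list alone (camera adjusted p = 1.4e-09, adjusted p = 0.077 with an estimated correlation). Genes of thymocytes were higher in the cortical arrays, Cd8a by 3.32 ± 0.13, adjusted p = 1.6e-08 at 1167 against 117, and Rag1 by 3.17 ± 0.23 over background at 459 against 51.1. All 6 immature thymocyte genes and all 7 T cell genes tested were higher, with the same numbers adjusted over the list alone (camera adjusted p from 2.3e-05 to 3.9e-04, adjusted p = 0.077 for each with an estimated correlation). The other marker lists that moved went down, from neutrophils, eosinophils, mast cells, platelets, macrophages, dendritic cells and blood endothelium to liver, fat, lung, skin and mesothelium (camera adjusted p from 9.2e-05 to 0.036, adjusted p from 0.077 to 0.22 with an estimated correlation). 7214 of 15042 probe sets, 3765 higher and 3449 lower, 3580 at least 2-fold differed.

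Medullary high cells of a further experiment were split by a GFP reporter (n = 3 each), which the labels do not tie to a gene. Aire was higher in GFP+ cells by 2.86 ± 0.17, adjusted p = 1.4e-06, at 4372 against 602. Dnmt3l, a cofactor of DNA methylation, was higher by 3.44 ± 0.15 and Csn2 by 2.00 ± 0.15. Lower in GFP+ cells were the channel gene Trpm5 (-4.08 ± 0.16, adjusted p = 1.8e-07), the taste transducin gene Gnat3 (-4.38 ± 0.31 to background) and the transcription factor gene Pou2f3 (-2.36 ± 0.27), known from tuft cells, for which no list was tested. Krt10, a keratin of differentiated skin, was lower as well (-2.65 ± 0.23). All 19 cell cycle genes tested were higher, 19 adjusted over the list alone (camera adjusted p = 2.3e-08, adjusted p = 0.42 with an estimated correlation). Keratinocyte genes were lower as a set, as 1 of 7 were higher and 5 lower (1 and 5 adjusted over the list alone), with camera adjusted p = 0.039, adjusted p = 0.42 with an estimated correlation. Of the peripheral tissue antigen genes 8 of 15 were higher and 3 lower (8 and 3 adjusted over the list alone), and the set test did not pass (camera adjusted p = 0.16, adjusted p = 0.56 with an estimated correlation). With a block for replicate number, epithelial and lung epithelial genes were lower as sets as well (camera adjusted p = 0.023 and 0.041, adjusted p = 0.63 and 0.63 with an estimated correlation). 6865 of 13889 probe sets, 4012 higher and 2853 lower, 1461 at least 2-fold differed.

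The knockout GFP+ cells were compared with GFP+ cells (n = 3 each). The labels do not name the gene knocked out, so the targeted gene could not be checked. Aire did not differ (-0.09 ± 0.17, adjusted p = 0.75), at 4101 against 4372, and where its probes lie against any deletion is not known here. Mucl2 was lower by a log2 change of -6.73 ± 0.30 to background, adjusted p = 1.1e-07, at 32.9 against 3499, and Ly6g, a surface protein of neutrophils, by -6.12 ± 0.15 to background. The casein gene Csn1s1 (-4.67 ± 0.16 to background) and the hormone genes Tac2 (-5.27 ± 0.18 to background) and Sst (-3.19 ± 0.12) were lower too. Ctla4, an inhibitory receptor gene, was higher by 2.97 ± 0.19, adjusted p = 1.1e-06, at 856 against 109. Of the peripheral tissue antigen genes 13 of 15 were lower (13 adjusted over the list alone), with camera adjusted p = 1.3e-14, adjusted p = 0.038 with an estimated correlation. Markers of several cell types were lower in the knockout, 6 of 7 for neutrophils (7 adjusted over the list alone) and 6 of 6 for hepatocytes (6 adjusted over the list alone), at camera adjusted p = 2.7e-09 and 1.2e-07, adjusted p = 0.038 and 0.091 with an estimated correlation. Those of macrophages, monocytes, eosinophils, red cells, platelets, fat, lung, skin and mesothelium were lower as lists too (camera adjusted p from 6.6e-06 to 0.022, adjusted p from 0.053 to 0.23 with an estimated correlation). Of 19 cell cycle genes limma called 0, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.38). 2647 of 13889 probe sets, 1306 higher and 1341 lower, 688 at least 2-fold differed, with 90 at least 2-fold higher and 598 at least 2-fold lower. The count was 1685 without knockout replicate 2.

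Lymph node stroma was sorted into fibroblastic reticular cells (FRC), lymphatic endothelial cells (LEC) and cells negative for both markers (DN), with and without complete Freund's adjuvant (CFA) for 6 days. Each group held n = 2 except LEC with CFA, which held 1 array and was not compared. LEC were set against FRC. Prox1, the transcription factor of lymphatic identity, was higher in LEC by 5.39 ± 0.19, adjusted p = 1.3e-08, Lyve1, a hyaluronan receptor, by 5.64 ± 0.42 and Cd36, a fatty acid receptor, by 6.75 ± 0.31 over background at 5269 against 49.0. The growth factor receptor gene Pdgfra (-5.50 ± 0.16, adjusted p = 7.7e-09), the chemokine gene Cxcl13 (-4.71 ± 0.34) and the collagen gene Col1a1 (-4.69 ± 0.24) were lower. Pdpn, which encodes the marker gp38 of both types, did not differ (-0.04 ± 0.24, adjusted p = 0.91). All 5 lymphatic genes tested were higher, 5 adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.22 with an estimated correlation). Of the stromal chemokine and cytokine genes 1 of 18 were higher and 15 lower (1 and 15 adjusted over the list alone), and of the fibroblast genes 7 of 8 were lower (7 adjusted over the list alone) (camera adjusted p from 1.2e-06 to 2.9e-06, adjusted p from 0.063 to 0.27 with an estimated correlation). Markers of blood endothelium (8 of 9), platelets (3 of 6) and mast cells (2 of 3) were higher in LEC (camera adjusted p from 1.2e-06 to 0.032, adjusted p from 0.27 to 0.34 with an estimated correlation), and those of monocytes lower, 3 of 4 (camera adjusted p = 0.043, adjusted p = 0.34 with an estimated correlation). 5201 of 14325 probe sets, 2338 higher and 2863 lower, 2287 at least 2-fold differed. Quantile normalization gave 2642 higher and 2550 lower.

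Whether CFA changed the stroma was asked in FRC and in DN cells. In DN cells Ace, the enzyme that makes angiotensin II, fell by a log2 change of -1.73 ± 0.20, adjusted p = 0.0051, from 1521 to 459. In FRC the called change, named after its values were seen, was Igkv6-20, an immunoglobulin light chain gene, which rose by 3.35 ± 0.18 over background, adjusted p = 3.4e-05 from 40.5 to 411. Pdpn did not change there (-0.16 ± 0.24, adjusted p = 0.8). Collagen and other matrix genes of DN cells moved up as a set with a median of 0.46 (camera adjusted p = 9.2e-06, adjusted p = 0.34 with an estimated correlation), although limma called 0 of 16 and 6 had an unadjusted p under 0.05. Their cell cycle genes moved up too (camera adjusted p = 1.1e-07, adjusted p = 0.34 with an estimated correlation), although limma called 0 of 18, 7 adjusted over the list alone. The cell cycle list also shifted up in FRC, with a median of 0.20 (camera adjusted p = 0.0025, adjusted p = 0.87 with an estimated correlation), although limma called 0 of 18 and 4 had an unadjusted p under 0.05. Monocyte markers moved up there as well (median 0.36, camera adjusted p = 0.0038, adjusted p = 0.69 with an estimated correlation), with 0 of 4 called and 2 at an unadjusted p under 0.05. Lists of other cells and of handling moved in DN cells as well. Monocyte genes moved up (median 0.50, 1 of 4 called, camera adjusted p = 0.025, adjusted p = 0.34 with an estimated correlation). The called gene was Hp, which is also in the acute phase list, so it does not mark monocytes alone. Platelet (median -0.34), blood endothelial (median -0.32), immediate early (median -0.26) and MHC class II genes (median -0.29) moved down, at camera adjusted p from 9.1e-05 to 0.011, adjusted p from 0.34 to 0.37 with an estimated correlation. A change in the cells sorted or in their handling was therefore not separated from the matrix and cell cycle shifts and the fall of Ace. DN cells changed 12 of 14325 probe sets, 10 up and 2 down, and 1442 had an unadjusted p under 0.05. Quantile normalization gave 10 up and 5 down, and the log2 of the intensity plus 32 gave 9 and 4. FRC changed 1 of as many, and 1942 had an unadjusted p under 0.05. A single fit of all arrays gave 121 for DN, 49 for FRC and 39 for the difference of the responses. FRC gave 5 without a filter on dim probe sets. The responses of FRC and DN cells differed for 12 probe sets, 3 higher and 9 lower in the FRC response, and Ace was among the higher (2.19 ± 0.28, adjusted p = 0.013). Platelet (median 0.53) and matrix genes (median -0.47) differed as sets (camera adjusted p from 9.7e-04 to 0.016, adjusted p from 0.6 to 0.86 with an estimated correlation). Ace was no longer called in DN cells without DN CFA replicate 1 (-1.66, adjusted p = 0.084) or DN replicate 2 (-1.61, adjusted p = 0.08). For the difference, it was not called without DN CFA replicate 1 or 2, DN replicate 2 or FRC replicate 1 (adjusted p = 0.1, 0.062, 0.082 and 0.061). The DN count was 315 without DN replicate 1. Without FRC CFA replicates 1 and 2 the FRC count was 3 and 9, and without FRC replicates 1 and 2 it was 5 and 2. For the difference, the count was 4 without DN CFA replicate 1 and 22 without DN replicate 1.

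Peritoneal macrophages of Gata6 knockout and control mice were compared (n = 3 each). The targeted gene Gata6 itself did not differ (0.02 ± 0.13, adjusted p = 0.93), at 2901 against 2855. Whether its probe set lies in the deleted part is not known, so the knockout label is not verified. Hgf, a growth factor gene of peritoneal macrophages, was lower in knockout cells (-1.43 ± 0.17, adjusted p = 0.0028), as was Aspa, an amino acid hydrolase (-1.30 ± 0.11). Mrc1, the mannose receptor, was higher by 4.81 ± 0.19, adjusted p = 5.3e-06, Folr2, a folate receptor, by 4.52 ± 0.15 and Ccr2, the chemokine receptor of monocytes, by 3.42 ± 0.25. Of the peritoneal macrophage genes 1 of 21 were higher and 7 lower (1 and 10 adjusted over the list alone, camera adjusted p = 4.4e-09, 0.032 with an estimated correlation). Of the tissue-resident macrophage genes 7 of 14 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 2.9e-04, 0.14 with an estimated correlation). Here and below this list includes Ccr2, also in the monocyte list. Of the cell cycle genes 18 of 20 were higher (19 adjusted over the list alone, camera adjusted p = 3.9e-13, 0.31 with an estimated correlation). Among them was Mki67, a marker of dividing cells (1.49 ± 0.21). 862 of 12882 probe sets, 624 higher and 238 lower, 235 at least 2-fold differed. Quantile normalization gave 616 and 419. The count was 467, 540 and 387 without knockout replicates 1, 2 and 3, and 440 and 501 without control replicates 2 and 3.

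Lung macrophages were split into alveolar cells and CD11c-CD11b+ cells (n = 3 each). Chil3, a chitinase-like lectin, was higher in alveolar cells by 7.63 ± 0.25 over background, adjusted p = 8.5e-13, at 6409 against 32.3, the carbonic anhydrase gene Car4 by 6.55 ± 0.11 and Siglecf, a sialic acid receptor, by 4.13 ± 0.14. The sort markers followed their gates, with Itgax, which encodes CD11c, higher by 5.92 ± 0.30 and Itgam, which encodes CD11b, lower (-4.93 ± 0.16). Cd209f, a lectin gene, was lower by a log2 change of -8.36 ± 0.14 to background, adjusted p = 7.2e-16, as were Lyve1 (-6.83 ± 0.10) and the complement gene C1qc (-7.16 ± 0.29 to background). All 14 alveolar macrophage genes tested were higher, 14 adjusted over the list alone. Of the tissue-resident macrophage genes 13 of 14 were lower (13 adjusted over the list alone), and of the interferon response genes 12 of 13 were lower (12 adjusted over the list alone). The lists moved as sets (camera adjusted p from 7.0e-15 to 6.5e-08, adjusted p from 0.0033 to 0.032 with an estimated correlation). Immediate early genes were lower too, as 2 of 16 were higher and 12 lower (2 and 13 adjusted over the list alone), with camera adjusted p = 2.2e-05, 0.15 with an estimated correlation. Some other marker lists were lower in alveolar cells, 5 of 5 for lung epithelium, 4 of 5 for platelets and 5 of 6 for fibroblasts (5, 4 and 5 adjusted over the list alone), at camera adjusted p = 0.0093, 0.0032 and 0.035, and 0.15, 0.049 and 0.15 with an estimated correlation. The platelet list includes Pf4, at 11213 in CD11b+ cells, so it does not show platelets. General epithelial genes were higher, 3 of 5 (3 adjusted over the list alone, camera adjusted p = 0.025, 0.2 with an estimated correlation). 7425 of 13954 probe sets, 4603 higher and 2822 lower, 2226 at least 2-fold differed.

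CD11c-CD11b+ lung macrophages against lung monocytes (n = 3 each) were compared next. Cd209f was higher by 8.37 ± 0.14 over background, adjusted p = 7.1e-16, Pf4, a chemokine, by 7.71 ± 0.10 over background and Lyve1 by 6.72 ± 0.10. Ccr2 was lower (-4.76 ± 0.23, adjusted p = 1.8e-10), at 152 against 4116, as was Plac8, a gene of monocytes (-6.03 ± 0.40). Of the tissue-resident macrophage genes 11 of 14 were higher and 2 lower (11 and 2 adjusted over the list alone), with camera adjusted p = 3.8e-08, adjusted p = 0.028 with an estimated correlation. Monocyte genes went down, as 1 of 7 were higher and 6 lower (1 and 6 adjusted over the list alone), with camera adjusted p = 6.4e-05, adjusted p = 0.093 with an estimated correlation. In the interferon list 12 of 13 were lower (12 adjusted over the list alone), with camera adjusted p = 3.8e-08, adjusted p = 0.041 with an estimated correlation. Lung epithelial genes were higher in the macrophage arrays, 5 of 5 (5 adjusted over the list alone), as were fibroblast genes, 4 of 6 (5 adjusted over the list alone), at camera adjusted p from 0.0011 to 0.016, adjusted p = 0.093 for each with an estimated correlation. 6793 of 13954 probe sets, 2834 higher and 3959 lower, 1948 at least 2-fold differed.

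Monocytes of skin-draining lymph node were set against those of lung (n = 3 each). Cxcl10, an interferon-induced chemokine, was higher in lymph node by 3.07 ± 0.24, adjusted p = 1.8e-06, at 9221 against 1096, and Cd274, which encodes PD-L1, by 2.84 ± 0.17. Dnase1l3, a secreted nuclease, was higher by 3.48 ± 0.13. Cd36 was lower (-2.38 ± 0.22), as was Cyp51, an enzyme of cholesterol synthesis (-1.94 ± 0.17). Of the interferon response genes 12 of 13 were higher (13 adjusted over the list alone), and of the cholesterol synthesis genes 10 of 11 were lower (11 adjusted over the list alone) (camera adjusted p = 3.6e-14 and 1.0e-14, adjusted p = 0.015 and 0.12 with an estimated correlation). Immediate early and stress genes moved as well, as 1 of 16 were higher and 7 lower (2 and 8 adjusted over the list alone), with camera adjusted p = 0.0015, adjusted p = 0.51 with an estimated correlation. 1781 of 13954 probe sets, 791 higher and 990 lower, 276 at least 2-fold differed. The count was 1176 and 1091 without lymph node replicates 1 and 3, and 1018 and 962 without lung replicates 1 and 2.

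Liver macrophages high for F4/80 were compared with those of intermediate F4/80 (n = 3 each). The groups follow the titles, while the markers of the intermediate arrays read F480lo. Adgre1, which encodes F4/80, was higher by 0.70 ± 0.13, adjusted p = 0.0057, at 6073 against 3727, and Marco, a scavenger receptor, by 1.30 ± 0.19. The lectin gene Cd209a was lower (-3.68 ± 0.27, adjusted p = 1.5e-04), at 116 against 1481, as was Ccr2 (-2.51 ± 0.27). Tie1, a receptor of endothelium, and Kit, a receptor of mast cells and progenitors, were lower too (-1.93 ± 0.12 and -1.63 ± 0.10). Of the Kupffer cell genes 14 of 16 were higher (14 adjusted over the list alone), with a median of 0.73 and camera adjusted p = 4.8e-07, adjusted p = 0.13 with an estimated correlation. General macrophage genes moved alike, as 8 of 9 were higher (8 adjusted over the list alone), with a median of 0.63 and camera adjusted p = 4.0e-04, adjusted p = 0.21 with an estimated correlation. Of the blood endothelial genes 8 of 9 were lower (8 adjusted over the list alone), with camera adjusted p = 1.8e-09, adjusted p = 0.16 with an estimated correlation. Markers of mast cells (3 of 3), neutrophils (3 of 5), T cells (2 of 3), monocytes (2 of 5) and platelets (1 of 6) were lower too (camera adjusted p from 2.3e-04 to 0.014, adjusted p from 0.13 to 0.31 with an estimated correlation). In the dendritic cell list 1 of 8 were higher and 6 lower (1 and 7 adjusted over the list alone), with camera adjusted p = 3.5e-05, adjusted p = 0.13 with an estimated correlation. With a block for replicate number, lists of tissue-resident macrophages, immediate early genes and fibroblasts also passed downward (camera adjusted p = 0.026, 0.043 and 0.023, adjusted p = 0.47, 0.59 and 0.47 with an estimated correlation). Those of interferon response and eosinophils passed upward (camera adjusted p = 0.033 and 0.043, adjusted p = 0.47 and 0.33 with an estimated correlation). 2619 of 12965 probe sets, 1385 higher and 1234 lower, 685 at least 2-fold differed, with 96 at least 2-fold higher and 589 at least 2-fold lower. The count was 1720 and 1564 without F4/80 high replicates 2 and 3, and 1630 without F4/80 intermediate replicate 3.

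In visceral fat, CD11b+ dendritic cells (n = 3) were compared with CD11b- dendritic cells (n = 2). Clec9a, a receptor for dead cells on cross-presenting dendritic cells, was lower in CD11b+ cells (-6.34 ± 0.29, adjusted p = 3.2e-06), at 89.8 against 7257, and the chemokine receptor gene Xcr1 by a log2 change of -5.76 ± 0.26. Itgam was higher by 4.26 ± 0.25, adjusted p = 1.3e-05, at 3391 against 177, the secreted protein gene Retnla by 6.99 ± 0.22 over background and Mrc1 by 4.83 ± 0.21. Of the Xcr1+ dendritic cell genes 9 of 11 were lower (9 adjusted over the list alone), and of the Sirpa+ dendritic cell genes 7 of 10 were higher (7 adjusted over the list alone) (camera adjusted p from 4.4e-11 to 2.0e-10, adjusted p = 0.029 for each with an estimated correlation). Of the macrophage genes 7 of 9 were higher (8 adjusted over the list alone), with camera adjusted p = 4.4e-11, adjusted p = 0.052 with an estimated correlation. Platelet markers were higher as well, 2 of 4 (2 adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.16 with an estimated correlation). 2200 of 13977 probe sets, 758 higher and 1442 lower, 1443 at least 2-fold differed, 5748 in a single fit of all arrays, and 788 and 751 without CD11b- replicates 1 and 3. Replicate numbers go with the age in days across the fat groups, and a block for the number gave 629, on 2 residual degrees of freedom. With it the Xcr1+ and Sirpa+ lists gave adjusted p = 0.26 and 0.25 with an estimated correlation. Monocyte and immediate early genes then passed upward (camera adjusted p = 0.011 and 0.025, adjusted p = 0.27 and 0.36 with an estimated correlation).

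Fat macrophages were set against CD11b+ dendritic cells (n = 3 each). Cd209f was higher in macrophages by 7.73 ± 0.31 over background, adjusted p = 3.5e-06, at 6361 against 29.9, Lyve1 by 5.99 ± 0.25 and Folr2 by 5.57 ± 0.27. Itgax was lower (-3.24 ± 0.62), as was the cytokine gene Il6 (-4.11 ± 0.59). Of the tissue-resident macrophage genes 9 of 14 were higher (9 adjusted over the list alone), with camera adjusted p = 3.8e-07, adjusted p = 0.18 with an estimated correlation. Adipocyte genes were higher too, 2 of 4 (3 adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.46 with an estimated correlation). 2178 of 13977 probe sets, 1262 higher and 916 lower, 1179 at least 2-fold differed, 5531 in a single fit of all arrays, and 1027 without macrophage replicate 4. The block for replicate number gave 958, and with it MHC class II genes passed downward (camera adjusted p = 0.0063, adjusted p = 0.67 with an estimated correlation).

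Mast cells of skin (n = 3) were compared with those of the peritoneal cavity (n = 4). Kit did not differ (-0.17 ± 0.15, adjusted p = 0.42), at 7991 against 9019. Fcer1a, a chain of the IgE receptor, was lower in skin (-2.17 ± 0.15, adjusted p = 9.7e-07), at 1762 against 7954, as was the lipoxygenase gene Alox5 (-5.69 ± 0.24). Il3, a growth factor of mast cells, was higher in skin by 6.45 ± 0.17 over background, adjusted p = 3.8e-10, at 2301 against 26.3, and Nr4a3 by 6.25 ± 0.15. Immediate early and stress genes were higher, 15 of 16 (16 adjusted over the list alone, camera adjusted p = 3.2e-16, 0.2 with an estimated correlation). Handling was not separated from this, and 1 digested peritoneal array was not compared. Of the Mrgpr peptide receptor genes 4 of 6 were higher and 1 lower (4 and 1 over the list alone, camera adjusted p = 0.0031, 0.21 with an estimated correlation). Mast cell genes went both ways, 2 of 10 higher and 3 lower (3 and 3 over the list alone, camera adjusted p = 0.67). Fibroblast genes were higher in skin arrays, 2 of 6 (2 over the list alone, camera adjusted p = 0.0031, 0.37 with an estimated correlation). 4185 of 13363 probe sets, 1697 higher and 2488 lower, 1519 at least 2-fold differed. The labels give blood as the source of peritoneal replicates 5 and 6.

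Blood eosinophils (n = 3) were set against blood neutrophils (n = 4). Ccr3, the eotaxin receptor, was higher in eosinophils by 5.72 ± 0.30, adjusted p = 7.1e-07, at 8127 against 154, and Il5ra, the receptor of their growth factor, by 5.31 ± 0.22 over background. S100a8, an antimicrobial protein of neutrophils, was lower (-5.78 ± 0.48, adjusted p = 1.6e-05), at 212 against 11621, as were the collagenase gene Mmp8 (-6.22 ± 0.27) and the chemokine receptor gene Cxcr2 (-5.86 ± 0.54). All 5 eosinophil genes tested were higher, 5 adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.23 with an estimated correlation). Platelet markers were higher in the eosinophil arrays as well, 3 of 4 (3 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.23 with an estimated correlation), at a median of 1.11. Of the neutrophil genes 1 of 11 were higher and 10 lower (1 and 10 adjusted over the list alone), and of the interferon response genes 10 of 12 were lower (10 adjusted over the list alone) (camera adjusted p from 7.6e-07 to 1.9e-06, adjusted p = 0.23 for each with an estimated correlation). 4834 of 13672 probe sets, 1862 higher and 2972 lower, 2145 at least 2-fold differed. Quantile normalization gave 2185 higher and 2208 lower. A single fit of all arrays gave 7665.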

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

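The tests of Xist and of the liver sort and the other splits of the arrays were chosen only after the results were seen, while those of thymocyte transcripts were fixed before.

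Cortical epithelium (8 weeks, n = 2) held thymocyte transcripts well above medullary high cells, for example Rag1 at 459 against 51.1 and Cd8a at 1167 against 117, with 9994 and 6466 in adult CD69- thymocytes. Of 252 genes at least 8-fold higher in those thymocytes than in medullary high cells, 90.1% were higher in the cortical arrays, against 57.1% of 9023 other genes, and 88.5 and 89.7% in each cortical array alone. The excess came to a median of 6.41% of the thymocyte level, with quartiles 2.70-fold apart, and the 10 most abundant genes reached 4.08 to 16.2%. In cortical Sca1+ cells the share of genes was 56.7% and in medullary low cells 38.5%. A candidate explanation is thymocytes or their RNA in the cortical sort, although the labels exclude CD45+ cells, and expression by the epithelium itself was not tested.

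Xist, a transcript of the inactive X chromosome, was held by 17 of the 133 arrays labelled male, at 1247 to 2393, while the others lay at 58.0 or below. Of these, 9 were CD8 T cells of spleen after Listeria (all 6 Tbet arrays, KLRG1+ replicate 2 and CD127+ replicates 1 and 2) and 8 were fetal gamma delta thymocytes. Transcripts of the Y chromosome (Eif2s3y, Kdm5d and Uty) lay under 20% of the median of the other male arrays in 7 of the 17, and at most at 22.9% in the 9 CD8 arrays, so cells of female origin may have been used there. The 8 fetal arrays kept them at 45.1% or more, up to 112%, which is consistent with pooled embryos of both sexes. The Tbet groups match in this, and within the KLRG1 groups replicate 3 of each differs from the rest.

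Liver macrophages of intermediate F4/80 held more of the markers of other cells than F4/80 high cells, with Tie1 of endothelium lower in the high cells by a log2 change of -1.93 and Kit by -1.63. The medians of 10 marker lists spread from -1.61 for mast cells to 0.85 for eosinophils, a span of 2.46. Monocyte genes fell by a median of 0.42. This leaves a lower share of macrophages open, since cell types may enter unequally. Of the Kupffer cell genes 6 of 16 (37.5%) lay more than 2 standard errors from their median of 0.73. Dilution of macrophage RNA forbids this only if no other cell holds them. The general macrophage list moved by a similar median of 0.63. Dilution may account for part or all of the shift, which is not shown to be particular to Kupffer cell genes. A few particular cell types in the gate, and macrophages that express these genes themselves, stay open, although the gate on CD45, CD64 and Mertk would remove endothelium.

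In blood neutrophils (n = 4), replicate 6 lay apart in Ccr3, at a log2 intensity of 8.20 against a median of 7.00, with a gap of 0.879 of the range, past the limit of the Dixon test at 0.05. It was the only such value of 12 looked at in 2 groups, and chance gives about 1 in 20. The responses of CD8 and CD4 cells at 24 h differed for 95 probe sets by the test of the difference itself. Among them were Gzmb (4.00, with CD4 cells at background), Xcl1 (3.66), Ccl3 (2.40) and Tigit (2.33), stronger in CD8 cells. Il2rb (-2.71) and Tnfrsf4 (-1.86) responded more in CD4 cells, and Itgae (-2.66) fell in CD8 cells, while CD4 cells held it at 60.2 and 60.5, near the floor of 58.0, where a fall could not have been seen. The responses of FRC and DN cells to CFA differed for 12 probe sets, among them Ace (2.19), which fell in DN cells.

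Other splits of the same arrays into groups of the same sizes were counted wherever both groups held 3 or more. For mast cells, of 35 splits only 1, the real one with 4185 probe sets, gave as many, and the highest other gave 1315. For granulocytes, again 1 of 35 gave as many, with 4834 against 0 for the highest other. Every other split mixes the real groups, which widens the spread and lowers the count, so chance is not excluded. For 12 comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Their real counts ran from 83 (Vg2+) to 7425 (alveolar), and the highest other split gave 0 by limma in each. For GFP and liver, whose equal replicate numbers deviated alike, the 4 splits that part as many pairs of equal numbers, the real one included, gave no other call.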

How the results depend on the processing

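The block for Xist, the leaving out of 2 arrays without Xist, the crossed block and the leaving out of X and Y genes were tests chosen only after seeing the data, and all other alternatives were fixed before the data were examined. Of 175 named changes (168 called), 2153 of 2159 refits kept the result and none reversed. The 6 that lost the call were leave-outs of Ace with CFA. They gave -1.66 and -1.61 against -1.73 in DN cells, and 2.00 to 2.25 against 2.19 for the difference. The names were picked from these results, so typical calls are not covered. Why counts moved was not tested, though the stricter filter tests fewer probe sets and a leave-out uses fewer arrays.

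Without a filter on dim probe sets the count moved by more than 1.5 times to 5 for FRC with CFA, 4326 for the medullary knockout and 33 for KLRG1. The stricter filter gave 3456 for LEC against FRC, 1412 for the medullary knockout, 4134 for GFP, 731 for Tbet, 4904 for alveolar macrophages, 1658 for CD24lo cells, 3334 for medullary high against low and 4174 for cortical against medullary cells. All arrays of the series in a single fit gave 49 for FRC with CFA, 121 for DN with CFA, 39 for the difference of these responses, 1036 for KLRG1, 5531 for fat macrophages, 5748 for fat dendritic cells, 7665 for granulocytes, 2841 for fetal thymocytes, 1350 for CD24lo cells and 47 for Vg2+ cells. Trend and robust variances gave 79 for KLRG1. Quantile normalization and the offset of 32 moved no total by more than 1.5 times, but the higher or lower calls alone moved further for CD4 cells at 1 and 48 h, memory against effector cells, Gata6 and DN with CFA. The block for replicate number gave 32 for DN with CFA, 127 for KLRG1, 2215 for memory against effector CD4 cells, 958 for fat macrophages and 629 for fat dendritic cells. For the comparisons whose equal replicate numbers deviated alike, the block gave 7979 for GFP and 3175 for liver, within 1.5 times. The list tests it changed stand beside these results. The block for Xist gave 37 for KLRG1, of which 35 were among the 50, and the 3 arrays with Xist gave 8. For fetal thymocytes 4261 were called without X and Y genes, 4257 of them among the 4376, and the crossed block gave 7041 for cortical against medullary cells. Of the 241 list shifts, 70 passed with an estimated correlation.

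Leaving out each replicate in turn gave these lowest and highest counts, 387 and 1048 for Gata6, 1397 and 2899 for CD4 at 1 h, 2934 and 4382 for CD4 at 48 h, 958 and 1375 for CD8 at 1 h, 2268 and 2719 for CD8 at 48 h, and 47 and 115 for the difference at 24 h. In stroma they were 2 and 9 for FRC with CFA, 9 and 315 for DN with CFA, and 4 and 22 for the difference. Effector and memory T cells gave 647 and 1528 for Tbet, 6 and 52 for KLRG1, 2573 and 4735 for effector CD4 cells, and 450 and 650 for memory CD4 cells. Macrophages, monocytes and dendritic cells gave 962 and 2478 for lymph node monocytes, 1564 and 2820 for liver, 1027 and 2281 for fat macrophages and 751 and 2624 for fat dendritic cells. In thymus they were 1685 and 2416 for the medullary knockout, 23 and 132 for Vg2+ cells and 1334 and 3446 for CD24lo cells. In the comparisons not listed here every leave-out stayed within 1.5 times.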

Other observations

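Arrays of 16 groups (20 arrays) entered no comparison, and their values are given without a test. In the single arrays of T cells cultured for 96 h, the cyclin gene Ccna2 stood at 131 in CD4 and 104 in CD8 cells, against 3464 and 3309 at 48 h, while Il2ra stood at 3896 and 3485. Gzmb stood at 288 in the CD8 array. The blood basophil array held Fcer1a at 3886, the integrin gene Itga2 at 4121 and the basophil protease gene Mcpt8 at 2731, with Kit at 179. A mast cell array labelled muscle held Kit at 10044 and Mcpt8 at 129. The eosinophil array of fat held Retnla at 5100, against 298 in blood eosinophils (range 122 to 1519).

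Blood monocytes titled 6+2- (n = 2) carry MHCII+ in their markers, and held H2-Ab1 at 620, against 8174 in the MHCII+ blood array. The splenic B1a array is labelled CD4+ CD8+ CD69+ and held the B cell gene Cd79a at 3625, with Cd4 at 94.6 and Cd3e at 156. In CD69+ thymocytes these stood at 44.1, 3190 and 9134. Medullary high cells of 5 weeks (n = 1) held Aire at 4298, near the 4074 of 8 weeks.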
